A study of Homo sapiens with 6 samples.

How the data were processed

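RNA of the A2780 ovarian cancer line was sequenced in 6 libraries, 1 for each of 6 groups. Per the labels' protocols, TMPyP4 was given at 5 µM, for 72 hours in the groups without H2O2, H2O2 was given at 200 µM for 2 hours from hour 46 and followed for 24 hours, and light described as 600 nm was given for 3 minutes at hour 48. No TMPyP4 time was recorded here for the combination groups. Differences between the combination and TMPyP4 alone may therefore hold a difference in TMPyP4 exposure beside that in H2O2. Poly(A) RNA was made into paired-end libraries with uracil-marked second strands and adapters that carry molecular identifiers, per the labels' protocols. The submitters' processing notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d, UMI-tools, DESeq2 and edgeR, without saying what each did. The same notes name the mouse build mm10, while the deposited table gives human Ensembl identifiers. All 99 of its identifiers matched GENCODE release 29 of the human genome (GRCh38), with start and end equal in 30 genes and within 1000 bp in 86, so positions are given as deposited and read as GRCh38.

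The deposited table held FPKM values and counts for each library, per the file headers. FPKM, as made by the authors, is relative to gene length and to the reads of the whole library. The counts deposited by the authors were whole numbers with no normalization, and whether reads were merged by molecular identifier before counting is not given in the sources used here. The table used here covered 99 genes in ascending order of Ensembl identifier, so its column sums are not depths. Relative depth was taken as the median over genes of count divided by FPKM, against the control. For 70 genes with a mean count of at least 100, between 97.1% and 100% of the ratios lay within 1% of the library's median. Exact Poisson 95% intervals of the counts cover counting error only.

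Columns were tied to samples by name. Only the H2O2 column carries the words of its sample's title. The control, TMPyP4 and combination columns were tied by abbreviation and elimination, and a suffix present in 1 member of each TMPyP4 and combination pair was read as light, since light is the step added between those samples. If that reading were wrong, dark and light would be exchanged in every statement, and the fitted H2O2 difference would stay as it is. Another 12 value columns of the table were not used.

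Tests, filters, gene lists, alternatives and the rule for named genes were fixed before the data were examined. Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are on that scale, which understates changes of low genes. The additive model had the background (no TMPyP4, TMPyP4 in the dark, TMPyP4 with light) and H2O2 as terms and left 2 residual degrees of freedom, so the error of each fitted value holds both the spread between libraries and any departure from additivity. Nothing in the labels says that libraries came from repeated cultures. The p values set each fitted difference against how far single libraries depart from the additive model, not against a spread between cultures. Single pairs and departures from additivity have 1 library per group, so they are given as sizes, with the number of genes at least 2-fold apart and no test. Correlations of log2 differences were taken across genes between pairs that share no library.

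The rule named, for H2O2, TMPyP4 in the dark and light, the 6 genes with the largest fitted difference on each side, with a mean of at least 5 FPKM and the same sign in every pair. As none passed the test, the places were filled by size, and fewer were named where fewer qualified. For the combination and the departures it named the 5 highest and 5 lowest genes with at least 5 FPKM in 1 or more of the libraries compared, and it added members of the fixed lists. A further 4 genes named by the rule were not analysed here. Of 34 gene lists, none had more than 2 measured members against a minimum of 5, so no list was tested.

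Alternatives were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, scaling by median ratio, to an equal sum or by quantiles, eBayes without trend or with robust variances, leaving out each library, and fitting H2O2 in fewer backgrounds. The scalings rest on the 99 genes of the table alone. The design assumed FPKM alone. As the table also held counts, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on them as alternatives chosen after seeing the data, and limma on FPKM stayed the reported test. The limma fit was tested on simulated data, with counts drawn for the 65 genes around their means with the dispersion edgeR estimated (0.0235). For the H2O2 comparison, over 20 simulated sets with 10 altered genes each, it called 66.2% of genes altered 1.5-fold, 98.3% of those altered 2-fold, 100% of those altered 4-fold and 0.909% of unaltered genes. These sets gave all genes the same dispersion, exactly additive differences and no shift of a whole library. The shares therefore need not hold for the real libraries, and 0 calls there do not exclude changes of these sizes. Terms of Gene Ontology and Reactome in the deposited annotation, with at least 5 tested members, were tested with camera in limma, a choice made after seeing the data. Single values of 2 genes picked by the naming rule are not reported here, and the correlation without single genes, first run with one of these left out too, was run again without MEOX1, ACSM3 and CD99 alone, with the same reading. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.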

Results

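A2780 is a line of human ovarian cancer cells. TMPyP4 is a cationic porphyrin that binds G-quadruplexes, the 4-stranded folds of guanine-rich DNA and RNA, and that acts as a photosensitizer under light. Cells were left untreated or received TMPyP4 at 5 µM, H2O2 at 200 µM, or both, and cells given TMPyP4 were kept dark or lit for 3 minutes. The 6 groups were the control, H2O2, TMPyP4 in the dark, TMPyP4 with light, the combination in the dark and the combination with light. Each group was 1 library, so no group has a spread of its own, and light without TMPyP4 was not sampled here.

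The table held 99 genes of each library, and the counts over these genes totalled 273811 in the control, 284757 with H2O2, 324980 with TMPyP4 in the dark, 257523 with TMPyP4 and light, 279100 in the dark combination and 274669 in the lit combination. These totals cover a small part of each library and are not its depth. The ratio of count to FPKM put the depths at 0.966, 1.003, 0.896, 0.973 and 0.925 times that of the control, in the same order. Of the 99 genes, 65 reached a mean of 1 FPKM and were tested, and 34 lay below it.

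The first comparison asked what H2O2 did to the cells, over 3 pairs of libraries that share no member: without TMPyP4, with TMPyP4 in the dark, and with TMPyP4 and light. MEOX1, a homeobox transcription factor gene (ENSG00000005102, chromosome 17, 43640389 to 43661922, minus strand), was lower with H2O2 in each pair: 7.37 against 16.4 FPKM without TMPyP4, 6.44 against 15.9 with TMPyP4 in the dark, and 10.3 against 13.6 with light. CD99, which encodes a cell-surface glycoprotein (ENSG00000002586, chromosome X, 2691187 to 2741300, plus strand), was lower in each pair as well, at 14.1 against 25.1 FPKM without TMPyP4. NDUFAB1, the mitochondrial acyl carrier protein and a subunit of respiratory complex I (ENSG00000004779, chromosome 16, 23581014 to 23596316, minus strand), was higher with H2O2 in each pair, at 32.4 against 12.2 FPKM without TMPyP4 and 36.5 against 28.0 FPKM in the dark. RECQL, a DNA helicase gene, stood at 17.0 against 8.57 FPKM without TMPyP4 and at 14.8 against 14.0 FPKM with light.

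Fitted over the 3 pairs, the log2 difference with H2O2 was −0.87 ± 0.18 (SE) for MEOX1, −0.57 ± 0.14 for CD99 and −0.38 ± 0.10 for DBNDD1. On the higher side it was 0.69 ± 0.23 for NDUFAB1, 0.44 ± 0.18 for RECQL, 0.40 ± 0.14 for LAS1L, a ribosome biogenesis factor, 0.40 ± 0.098 for the RNA helicase gene DHX33, 0.38 ± 0.15 for DPM1, a dolichol-phosphate mannosyltransferase subunit, and 0.39 ± 0.11 for the mannose 6-phosphate receptor gene M6PR, whose sign turned (−0.081) under quantile normalization. The values rest in part on the pair without TMPyP4: without the control or the H2O2 library NDUFAB1 fell to 0.37, RECQL to 0.21 and DPM1 to 0.23. None of these genes passed the test, with limma adjusted p values between 0.135 and 0.174. The smallest adjusted p, 0.119, belonged to ACSM3 (−1.01 ± 0.19) and ICA1 (0.54 ± 0.089), named after their values were seen because their mean lay below 5 FPKM. ACSM3, a medium-chain acyl-CoA synthetase gene, had 4.64, 4.57 and 3.28 FPKM without H2O2 and 1.84, 1.01 and 1.86 FPKM with it.

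By limma 0 of 65 genes passed an adjusted p of 0.05 for H2O2, and 17 had an unadjusted p under 0.05, 10 of them higher and 7 lower, where chance gives 3.25. The median fitted difference of the 65 genes was 0.13, and against that median NDUFAB1 stood at 0.57 and MEOX1 at −0.997. With libraries scaled to equal median ratios 17 genes again had such a p, 7 higher and 10 lower, and after quantile normalization 8 had, 3 higher and 5 lower. The count was 9 without any 1 of the 4 TMPyP4 libraries. On the deposited counts, edgeR called 0 genes with library sizes from the ratio of count to FPKM and 9 with TMM, and DESeq2 called 7. In the 4 dark libraries alone limma called 5: ACSM3, MEOX1 and CD99 on the lower side, NDUFAB1 and ICA1 on the higher side. In the 4 TMPyP4 libraries alone, which leave out the control and the H2O2 library, limma called no gene. Both fits keep 1 residual degree of freedom. In 36 of the 65 genes the difference had the same sign in all 3 pairs, 29 higher and 7 lower, where independent signs at the share of higher genes in each pair would give 33.6%. Across genes, which are not independent replicates, the log2 differences of 2 pairs correlated with a Pearson r of 0.71 between the dark and lit TMPyP4 backgrounds, 0.69 between no TMPyP4 and the dark background, and 0.52 between no TMPyP4 and the lit background.

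**Figure D1:**
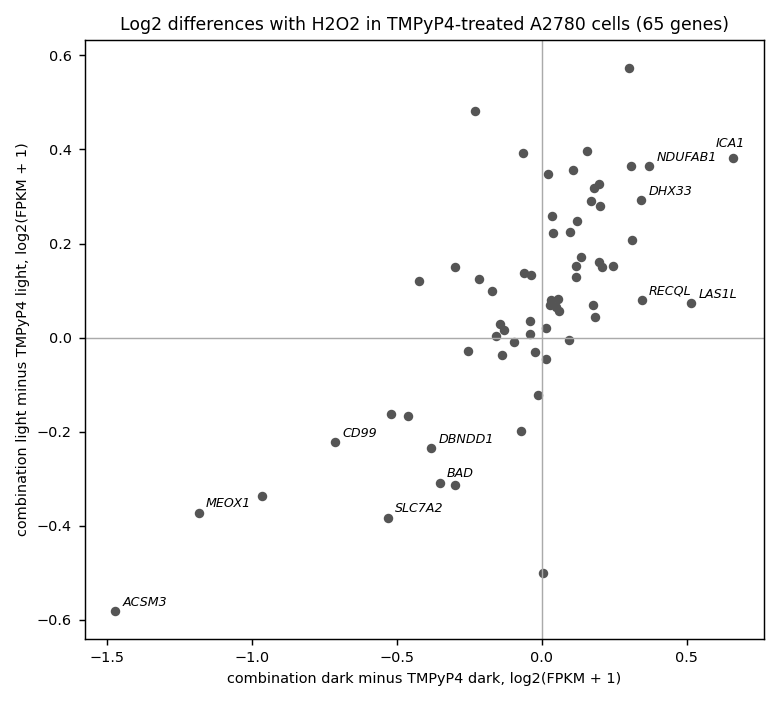
Each point is 1 of the 65 tested genes. The horizontal axis is the log2 difference in FPKM + 1 of the dark combination minus TMPyP4 in the dark, and the vertical axis is that of the lit combination minus TMPyP4 with light. ACSM3 (−1.47 and −0.58) and MEOX1 (−1.18 and −0.37) lie at the lower left, and ICA1 (0.66 and 0.38) at the upper right.

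The second comparison asked what TMPyP4 did in the dark, over 2 pairs: without H2O2 and with it. NDUFAB1 was 28.0 against 12.2 FPKM without H2O2 and 36.5 against 32.4 FPKM with it. SLC25A5, a mitochondrial ADP/ATP carrier gene (ENSG00000005022, chromosome X, 119468422 to 119471396, plus strand), had 207 against 108 FPKM without H2O2 but 212 against 198 FPKM with it. CIAPIN1, an iron-sulphur cluster assembly factor, had 15.4 against 8.49 FPKM without H2O2 and 16.8 against 14.1 FPKM with it. FKBP4, an HSP90 co-chaperone, had 35.8 against 24.9 and 42.6 against 34.7 FPKM. SLC25A5 has near-identical pseudogene copies, and how shared reads were counted is not given in the sources used here.

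The fitted log2 difference with TMPyP4 in the dark was 0.66 ± 0.28 (SE) for NDUFAB1, 0.51 ± 0.35 for SLC25A5, 0.51 ± 0.17 for CIAPIN1, 0.45 ± 0.22 for RECQL, 0.40 ± 0.13 for FKBP4 and 0.40 ± 0.17 for the apoptosis gene BAD. On the lower side it was −0.25 ± 0.17 for CD99, −0.17 ± 0.13 for DBNDD1 and −0.11 ± 0.22 for MEOX1, whose sign turned without the control or the dark combination library (0.031 and 0.13). After median-ratio scaling NDUFAB1 stood at 0.51, SLC25A5 at 0.36, CIAPIN1 at 0.36, RECQL at 0.31, FKBP4 at 0.24, BAD at 0.26, CD99 at −0.41, DBNDD1 at −0.31 and MEOX1 at −0.26. By limma 0 of 65 genes passed, the smallest adjusted p being 0.379, while 7 had an unadjusted p under 0.05, 6 higher and 1 lower. With median-ratio scaling 8 genes did, 4 higher and 4 lower. Neither edgeR nor DESeq2 called a gene here, with 0 in each of their fits. Without the control library NDUFAB1 fell to 0.17, SLC25A5 to 0.10, CIAPIN1 to 0.24, RECQL to 0.10, FKBP4 to 0.26, BAD to 0.16, CD99 to −0.093 and DBNDD1 to −0.062. Without the H2O2 library limma called 4: NDUFAB1, SLC25A5 and CIAPIN1 on the higher side and POLR2J on the lower side. The 2 pairs had the same sign in 42 of 65 genes, where independent signs at the share in each pair would give 51.3%, and their log2 differences correlated across genes with a Pearson r of 0.45.

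Light on TMPyP4-treated cells was compared in 2 pairs, without H2O2 and with it, taking the libraries marked for an added step as the lit ones. DBNDD1 was 8.46 against 6.81 FPKM and, with H2O2, 7.03 against 4.99 FPKM. ARF5, a gene of a small GTPase of the Golgi, was 30.9 against 26.6 FPKM and, with H2O2, 40.9 against 29.7 FPKM. KRIT1, whose loss underlies cerebral cavernous malformations, was 5.42 against 6.99 FPKM and, with H2O2, 5.58 against 6.77 FPKM. The start of KRIT1 overlaps that of ANKIB1 on the opposite strand, and whether counting used strand is not given in the sources used here.

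Fitted log2 differences with light were 0.35 ± 0.13 (SE) for DBNDD1, 0.33 ± 0.13 for ARF5, 0.25 ± 0.17 for the Wnt pathway gene DVL2, 0.22 ± 0.22 for WDR54, 0.21 ± 0.28 for NDUFAB1 and 0.15 ± 0.26 for POLR2J, an RNA polymerase II subunit gene with near-identical copies. They were −0.28 ± 0.11 for KRIT1, −0.26 ± 0.17 for the cationic amino acid transporter gene SLC7A2, −0.22 ± 0.22 for RECQL, −0.19 ± 0.13 for CDC27, a subunit of the anaphase-promoting complex, and −0.17 ± 0.15 for GCFC2. The limma test passed 0 of 65 genes at an adjusted p of 0.05, the smallest being 0.801, with 1 gene (DBNDD1) at an unadjusted p under 0.05, fewer than the 3.25 that chance gives. edgeR and DESeq2 also called 0. Without TMPyP4 in the dark SLC7A2 fell to −0.083, CDC27 to −0.037 and GCFC2 to −0.024, without the dark combination DVL2 fell to 0.022, without the lit combination ARF5 fell to 0.19, and the signs of WDR54, NDUFAB1, POLR2J and RECQL turned without 1 library or another (−0.0085, −0.033, −0.11 and 0.052). With quantiles ARF5 stood at 0.16, NDUFAB1 at 0.14, POLR2J at 0.31, CDC27 at −0.097 and GCFC2 at −0.11. Differences of the 2 pairs correlated across genes with a Pearson r of 0.22, and 44 of 65 genes had the same sign in both, where independent signs would give 47.0%.

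TMPyP4 with light against no TMPyP4 was fitted over 2 pairs. NDUFAB1 was 32.7 against 12.2 FPKM without H2O2 and 42.4 against 32.4 FPKM with it, a fitted log2 difference of 0.87 ± 0.28 (SE). It was 0.38 without the control library and 1.36 without the H2O2 library. Of genes named after their values were seen, CAMKK1 had 0.50 ± 0.10, BAD 0.50 ± 0.17 (0.26 without the control) and FKBP4 0.46 ± 0.13, and on the lower side CREBBP had −0.54 ± 0.16 (−0.35 without the control), CDC27 −0.35 ± 0.13 (−0.21 without the H2O2 library) and CFLAR −0.29 ± 0.11, each with a limma adjusted p of 0.232, the smallest in this comparison. By limma 0 of 65 genes passed and 13 had an unadjusted p under 0.05, 9 higher and 4 lower, against 14 after median-ratio scaling, 8 higher and 6 lower. With edgeR 0 passed with sizes from the ratio of count to FPKM and 4 with TMM (all lower, CFLAR, CDC27 and CREBBP among them), and DESeq2 called 2 (CAMKK1 and NDUFAB1, both higher). Without the H2O2 library, and likewise without the lit combination library, limma called 1 gene, NDUFAB1.

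The combined treatment was set against the control in single pairs of libraries, which have no replicate check. In the dark combination NDUFAB1 was 2.85 times the control on the FPKM + 1 scale, RECQL 2.11 times, SLC25A5 1.95 times, CIAPIN1 1.87 times and SNX11, a sorting nexin gene, 1.79 times. MEOX1 stood at 0.427, CD99 at 0.498 and POLR2J at 0.596 times the control. With light, NDUFAB1 was 3.30 times the control, SNX11 2.20 times, CIAPIN1 1.88 times, SLC25A5 1.87 times and LAP3, a leucine aminopeptidase gene, 1.87 times. CD99 stood at 0.579, POLR2J at 0.639 and MEOX1 at 0.648 times the control. Scaling moved some of these: with an equal sum the log2 differences with light went from 0.90 to 0.54 for SLC25A5, from 0.91 to 0.58 for CIAPIN1, from 0.91 to 0.56 for LAP3, from −0.65 to −0.99 for POLR2J and from −0.63 to −0.96 for MEOX1, and with quantiles that of POLR2J in the dark went from −0.75 to −1.20.

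At least 2-fold apart on that scale were 5 genes in the dark combination against the control (NDUFAB1, RECQL, MEOX1, CD99 and, named after its value was seen, ACSM3) and 2 in the lit combination (NDUFAB1 and SNX11). After median-ratio scaling the lit combination had 5. RECQL in the dark combination and SNX11 in the lit one lay under 2-fold with each scaling. Their log2 differences were 0.81 and 0.91 by median ratio, 0.80 and 0.86 with an equal sum, and 0.92 and 0.94 with quantiles. Against the control, 2 genes were that far apart with H2O2 (NDUFAB1 and MEOX1), 2 with TMPyP4 in the dark (NDUFAB1 and SNX11) and 1 with TMPyP4 and light (NDUFAB1), as deposited. After median-ratio scaling 5 were with H2O2 and 1 with TMPyP4 in the dark. The dark combination differed that much from TMPyP4 in the dark in 2 genes, MEOX1 and ACSM3. The other 5 single pairs had 0 such genes. Each treated library was higher than the control in 72.3% to 78.5% of the 65 genes, with median log2 differences of 0.18 to 0.35. After median-ratio scaling the share was 49.2% to 55.4% and the medians lay between −0.02 and 0.12. As that scaling levels the libraries on these same genes, the move follows from the scaling and does not tell why the control lay lower.

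**Figure D2:**
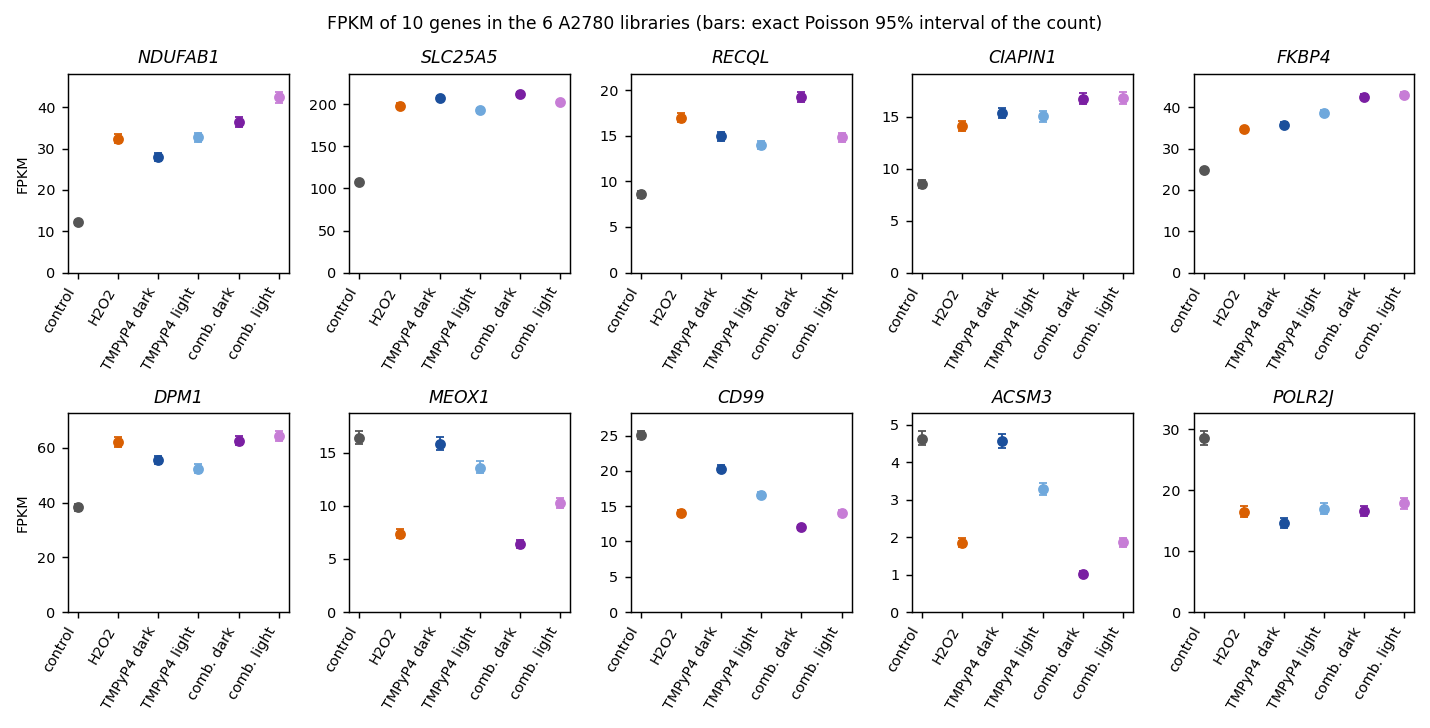
FPKM, from 0 on each vertical axis, of 10 genes in the 6 libraries, 1 point per library, with bars for the exact Poisson 95% interval of the count, which covers counting error only. NDUFAB1 runs from 12.2 in the control to 42.4 in the lit combination, SLC25A5 from 108 to between 193 and 212, and MEOX1 is lowest in the dark combination at 6.44.

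Whether H2O2 and TMPyP4 added up was read from the difference between the H2O2 differences with and without TMPyP4, on the log2 scale. For NDUFAB1 this departure was −0.97 in the dark and −0.98 with light: the H2O2 and dark TMPyP4 libraries had 32.4 and 28.0 FPKM, the dark combination 36.5 FPKM and the control 12.2 FPKM. In the dark it was −0.93 for SNX11, −0.84 for SLC25A5, −0.81 for TSPAN6 and −0.79 for WDR54, and on the other side 0.94 for POLR2J, 0.29 for CREBBP, 0.14 for DBNDD1, 0.076 for ARF5 and 0.076 for CD99. With light it was −0.83 for RECQL, −0.80 for TSPAN6, −0.80 for SLC25A5 and −0.64 for WDR54, and 0.83 for POLR2J, 0.68 for MEOX1, 0.57 for CD99, 0.48 for CREBBP and 0.32 for ARF5. The sizes moved with scaling: after median-ratio scaling the departures in the dark were 0.51 for CREBBP, 0.36 for DBNDD1, 0.31 for ARF5 and 0.31 for CD99, and with an equal sum −0.64 for NDUFAB1, −0.66 for SNX11, −0.49 for SLC25A5, −0.52 for TSPAN6 and −0.49 for WDR54. With light that of ARF5 was 0.51 with an equal sum, and that of CD99 was 0.86 with quantiles. As deposited, a departure of at least 2-fold was seen in 0 genes in the dark and in 1 with light, C1orf112 at −1.03, named after its value was seen. The departure of POLR2J in the dark passed 2-fold with each scaling: 1.17 by median ratio, 1.28 with an equal sum and 1.43 with quantiles. With light it was 0.99, 1.02 and 1.20 in the same order. In the dark 54 of 65 departures were negative, and with light 46 were, against 35 and 35 after median-ratio scaling. That scaling levels the libraries on these same genes, so a more even split of signs follows from it. Each departure rests on 4 single libraries, the control among them, and was not tested.

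Few members of the gene lists fixed beforehand were among the 99 genes. RECQL was the measured member of the list named G-quadruplex helicases, and whether it acts on G-quadruplexes was not examined here. GCLC came from the NRF2 targets, LIG3 from base excision repair, CYP51A1 from cholesterol synthesis and FKBP4 from the heat shock response. BAD and CASP10 came from the apoptosis list, CASP10 lying below the minimum. GCLC, a subunit of the enzyme limiting glutathione synthesis, had fitted log2 differences of 0.24 ± 0.13 (SE) with H2O2, 0.23 ± 0.17 with TMPyP4 in the dark and 0.19 ± 0.17 with light. LIG3, a DNA ligase gene, had 0.19 ± 0.091, 0.00091 ± 0.11 and 0.16 ± 0.11, and CYP51A1 0.031 ± 0.11, 0.21 ± 0.14 and 0.0087 ± 0.14, in the same order. BAD had −0.17 ± 0.14 with H2O2 and FKBP4 0.29 ± 0.11. None of these passed the limma test in any of the 4 effects, and no list held enough members to be tested as a group.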

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

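The tests on weakly detected genes were chosen after the result was seen. Groups held 1 library each, and no library was compared with others of its group.

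For 5 named genes the H2O2 difference had 1 sign without TMPyP4 and the opposite sign in both TMPyP4 backgrounds, as deposited; the difference between backgrounds was not tested. After median-ratio scaling or rescaling to an equal sum this held for CREBBP alone of the 5, and after quantile normalization for CREBBP and CDC27. POLR2J dropped out through its light value alone, −0.021 by median ratio, −0.022 with an equal sum and 0 with quantiles. Its value without TMPyP4 grew to −1.01, −1.04 and −1.20 in the same order. As deposited, BAD was 0.15 on the log2 scale without TMPyP4, −0.35 with TMPyP4 in the dark and −0.31 with light. POLR2J was −0.76, 0.18 and 0.069 in the same order. SLC7A2 was 0.039, −0.53 and −0.38. CDC27 was 0.13, −0.25 and −0.028, and CREBBP was −0.26, 0.038 and 0.22.

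Below the minimum for testing, 6 genes were above the control, beyond counting error, in both light libraries, and above the other 4 libraries, though in the combination the counting intervals of the lit and dark libraries overlapped for SKAP2, CD38 and SLC4A1. FUCA2, a fucosidase gene, had 1.22 FPKM (212 counts) with TMPyP4 and light and 0.845 FPKM (152 counts) in the lit combination, against 0.232 FPKM (46 counts) in the control, 0.389 with H2O2, 0.158 with TMPyP4 in the dark and 0.166 in the dark combination. SKAP2 had 0.245 FPKM with TMPyP4 and light against 0.0629 in the dark, 0.144 (50 counts) in the lit combination against 0.101 (37 counts) in the dark one, and 0.0262 in the control. The control had 0 counts of CD38, TMEM176A, PDK4 and SLC4A1. With TMPyP4 alone, lit against dark, CD38 had 0.0595 and 0.0126 FPKM, TMEM176A 0.0687 and 0.0136, PDK4 0.0728 and 0, and SLC4A1 0.0361 and 0. In the combination CD38 had 0.0574 (26 counts) and 0.0228 (12 counts), TMEM176A 0.0508 and 0, PDK4 0.0339 and 0, and SLC4A1 0.0830 (28 counts) and 0.0294 (11 counts).

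Of the 31 genes below the minimum with any count, 8 were higher in both light libraries than in the other 4, and the highest of the other 14 pairs of libraries had 3. The light pair was thus 1 of 15 pairs with as many, and 15 pairs are too few for a share under 0.05. Greater depth of the light libraries is argued against, since the deeper of them had 0.925 times the depth of the control and the shallowest other library 0.966. RNA of other cells or another library in the light libraries stays open: 0 tested genes were at least 2-fold higher in a light library than in its dark partner, but the labels name no source. The other 12 value columns of the table, which were not used, were not compared as a possible source. An effect of light on TMPyP4-treated cells may equally stand behind the higher values of these genes and was not tested apart from these alternatives.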

How the results depend on the processing

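Alternatives on the counts and the share of genes higher in each pair were chosen after seeing the data, and the others were planned. The limma count of 0 genes held for the light effect under all alternatives run. For H2O2 it became 3 after rescaling to an equal sum, 3 with robust variances, 5 in the dark backgrounds alone, 9 by edgeR with TMM and 7 by DESeq2, and it ranged from 0 to 5 when 1 library was left out (5 without TMPyP4 with light, 5 without the lit combination). MEOX1 and ACSM3 were each among the calls in 7 of these settings, but 3 of the 7 (without either light library, and the dark backgrounds alone) rest on the same 4 libraries. For TMPyP4 in the dark, leaving out 1 library gave 0 to 4 genes (4 without H2O2). For TMPyP4 with light it gave 0 to 1 (1 without H2O2 or without the lit combination), and the count was 2 after rescaling to an equal sum, 4 by edgeR with TMM and 2 by DESeq2. Fits without 1 library keep 1 residual degree of freedom and assume that lone libraries vary like the rest. Of the fits on counts only edgeR with sizes from count and FPKM called 0 genes for each effect. The TMM fit scales to these 65 genes alone. The count at an unadjusted p under 0.05, 17 for H2O2, was 8 after quantile normalization and ranged from 9 to 16 without 1 library, and 7 for TMPyP4 in the dark ranged from 1 (without the control) to 26 (without H2O2). For TMPyP4 with light the 13 became 0 without the TMPyP4 and light library and 20 without H2O2, and for light the 1 became 6 without the control or without H2O2. With no filter light had 10 such genes of 96.

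Numbers of genes at least 2-fold apart moved, from causes not tested beyond the scale of the control library. For H2O2 against the control 2 became 4 with a pseudocount of 0.1 and 5 with median-ratio scaling, an equal sum or quantiles. For the lit combination against the control 2 became 5 with the pseudocount, 5 with each of the 3 scalings and 1 with a minimum of 5 FPKM. For TMPyP4 in the dark against the control 2 became 1 with that minimum, with median-ratio scaling and with an equal sum. For TMPyP4 with light against the control 1 became 2 with an equal sum and 2 with quantiles. For the dark combination against TMPyP4 in the dark 2 became 1 with the minimum of 5. Departures in the dark went from 0 to 2 with the pseudocount, 1 with median-ratio scaling, 1 with an equal sum and 2 with quantiles. Departures with light went from 1 to 2 with the pseudocount, 0 with the minimum of 5, 0 with median-ratio scaling and 3 with quantiles.

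Signs of named genes that turned were M6PR with H2O2 (−0.081 with quantiles), MEOX1 with TMPyP4 in the dark (0.031 without the control and 0.13 without the dark combination, within −0.34 to 0.13 over all 6) and, for light, WDR54 (−0.0085 without the dark combination, up to 0.46 without TMPyP4 in the dark), NDUFAB1 (−0.033 without TMPyP4 with light, −0.028 without the dark combination, up to 0.46 without the lit combination), POLR2J (−0.11 without TMPyP4 in the dark, −0.025 without the lit combination, up to 0.42 without the dark combination) and RECQL (0.052 without the lit combination, down to −0.49 without TMPyP4 with light). In 549 other fits of genes picked by the naming rule the sign and the side of the threshold stayed, though not always the size, in 24 the gene passed and in 1 the value was 0 (SLC25A5 with quantiles, fixed by its rank of 1 in all 6 libraries). The 5 correlations between pairs stayed within their 95% intervals in all 15 refits. Without 1 library or another, values of kept sign shrank over 1.5 times for 3 of 11 genes with H2O2. For TMPyP4 in the dark 9 of 10 did, and for light 8 of 12. Values grew so in 0, 9 and 13 fits. Tests of gene lists were not run.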

Other observations

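The terms of the deposited annotation, the scale of the control and the search for single genes behind a correlation were examined only after the results were seen.

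The term mitochondrion, picked after 34 terms had been seen, did not pass. Of its 13 tested genes, NDUFAB1, SLC25A5 and CIAPIN1 among them, 12 had a higher fitted value with TMPyP4 in the dark, as had 47 of all 65 genes (10 of 13 and 33 of 65 after median-ratio scaling, 8 of 13 and 33 of 65 after quantile normalization). The median log2 was 0.32 against 0.09 for the other genes, with a camera adjusted p of 0.225 in limma over 34 terms and an adjusted p of 0.995 with an estimated correlation. With H2O2 11 of the 13 and 47 of the 65 were higher, against 10 and 36 after median-ratio scaling (median 0.22 as deposited against 0.10, camera adjusted p of 0.645, and adjusted p of 0.975 with an estimated correlation). With TMPyP4 and light 12 of the 13 and 44 of the 65 were higher, against 12 and 34 after that scaling (camera adjusted p of 0.125, and 0.991 with an estimated correlation). For light 6 of the 13 were higher. No term passed for any effect.

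MEOX1, ACSM3 and CD99 were lower with H2O2 by more in the dark TMPyP4 background than in the lit one: MEOX1 stood at −1.18 and −0.37, ACSM3 at −1.47 and −0.58, and CD99 at −0.71 and −0.22 on the log2 scale. These genes were chosen after their values were seen, and the difference between backgrounds was not tested. Over all 65 genes, these included, the H2O2 differences had an SD of 0.36 in the dark background and 0.24 in the lit one. The larger difference in the dark was therefore not shown to be particular to MEOX1, ACSM3 and CD99.

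The control library was the highest or the lowest of the 6 in 50 of 65 genes, lowest in 43, where chance gives 21.7. The mean of the 5 treated libraries minus the control went with gene length across genes (Spearman rho of −0.51) and less with GC content (−0.066). A linear fit on both took up 16.8% of the variance of that difference across genes. With each library's trend on both removed and its mean kept, the control was extreme in 47 genes and the highest other library in 21. As that kept mean holds the control's low level, these counts cannot decide whether length or GC content accounts for the pattern. A difference of scale in the control library remains possible for part of it: after median-ratio scaling the control was extreme in 38 genes, 19 on each side, against 27 for the lit combination, which decides neither way. After rescaling to an equal sum the control was extreme in 38 genes against 24 for the lit combination. With quantiles the counts were 32 for the control and 22 for the dark combination, the highest other library. Whether 1 deviating control library or the treatments lie behind the pattern cannot be told apart, because the control enters every difference from untreated cells, and the 54 negative departures in the dark (35 after median-ratio scaling, 28 after rescaling to an equal sum and 32 with quantiles) do not part them, so a shared response to H2O2 and TMPyP4 stays open.

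The Pearson r across genes of the H2O2 differences in the dark and lit TMPyP4 backgrounds, 0.71, involves no control library. It was 0.71 after linear trends on gene length and GC content were removed, and 0.62 without MEOX1, ACSM3 and CD99. Neither such a linear trend nor these 3 genes thus account for all of the relation. Trends of another shape and other leading genes are not covered by these checks. As limma called 0 genes for H2O2, each of the 10 splits of the 6 libraries into 3 and 3 must give as many, which says nothing of chance. By genes at an unadjusted p under 0.05 the real split had 17 and was 1 of 10 with as many, but the highest other value, 15 (with 2 adjusted calls), is 1 fit of H2O2 against the control that 2 splits share, and of the 4 splits that part the libraries of each background the others gave at most 2, so the splits are too few for a share under 0.05. A response to H2O2 that recurs with and without light may lie behind the relation. A difference in TMPyP4 exposure shared by both pairs may as well, since no TMPyP4 time was recorded here for the combination groups. The hypothesis of a response to H2O2 rests on 1 library per group, and repeated cultures with equal TMPyP4 exposure would test it.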
